A study of Mus musculus with 4 samples.

How the data were processed

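Poly(A)-selected RNA was sequenced from intestinal epithelial cells of C57BL/6 mice, sorted by GFP into a GFP-high fraction, which the labels call intestinal stem cells, and a GFP-low fraction, which they call progenitors. The mice were 71-week-old males on a high-fat diet (HFD) or the control diet. Per the labels' protocols, each library came from sorted cells pooled from 2 to 5 mice, and strand-specific libraries were made with a dUTP kit and sequenced on a HiSeq instrument. The gene that drives GFP and the composition of the diets are not given in the sources used here. There were 4 libraries, 1 for each diet and fraction, so no group has a replicate. The labels do not say whether both fractions of a diet came from the same mice.

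The deposited values are counts of reads per gene, not normalized. The submitters' processing notes name cutadapt, TopHat version 1.4.1 and HTSeq, and the genome builds GRCm38 and mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so genes on opposite strands of the same interval, and near-identical genes such as the alpha-defensins and the MHC genes, may share reads. Each table held 38124 gene IDs, of which 36345 matched a symbol in the reference table and 1779 did not. The IDs without a symbol held between 1.88% and 2.39% of the counts of a library. No row without a gene name was present. Gene positions were taken from GENCODE release M21 on GRCm38.

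The libraries held 6207080 counts (HFD, GFP-high), 5327015 (HFD, GFP-low), 5201394 (control, GFP-high) and 4677389 (control, GFP-low). A gene with 0 counts in a library can be as high as 0.449 to 0.680 CPM (counts scaled to a common library size of 1e6) in it, from an upper limit of 3 counts. The reads carry no molecular identifiers, so intervals and limits throughout cover counting error only.

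Library sizes were scaled with the TMM method of edgeR version 4.0.16 in R version 4.3.3. The 10694 genes with at least 20 counts in at least 2 libraries were tested with edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A single additive model with diet and fraction as terms was fitted to all 4 libraries. It leaves 1 residual degree of freedom, the diet-by-fraction term, and the spread was shared across genes by empirical Bayes. The common dispersion was 0.00695, a biological coefficient of variation of 0.0833. Standard errors were computed from the fold change and the F statistic. A real diet-by-fraction difference counts as spread in this model and lowers the power for the genes that have it. P-values measure only the spread between these libraries, which may be technical, and those for diet are too small if both fractions of a diet came from the same mice.

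Within a fraction, HFD was set against control with 1 library each and without a test. The log2 ratio was that of TMM-scaled CPM with 0.5 CPM added to each value, which understates the size of changes in low genes. Genes were counted when they differed by at least 2-fold on that scale and had at least 5 CPM in the higher library. Intervals are exact 95% intervals for the ratio of Poisson counts. The number of genes counted in both fractions was set beside the number that independent lists would share. Mean log2 ratios for diet, for fraction and for the diagonal (the halved diet-by-fraction difference) were counted by the same rule. The spread of the log2 ratio of GFP-high over GFP-low was computed in each diet from counts thinned to the shallowest library.

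The analysis used 25 gene lists, described in the results by cell type or pathway. For each list with at least 3 tested members, the median log2 ratio was given with an interval from 200 Poisson redraws of the counts and with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe these libraries only. Called members were counted over all tested genes and adjusted over the list alone. The comparisons, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named the 10 higher and 10 lower genes with the largest size of the smaller of their 2 log2 ratios, for fraction among called genes and for diet over both fractions, at 10 CPM or more in 2 libraries. It added the 5 higher and 5 lower genes in each fraction at 10 CPM or more in the higher library, the 2 highest and 2 lowest members of a list, and genes fixed by name, among them Lgr5, Olfm4, Cpt1a, Pdk4, Angptl4, Jag1, Jag2, Lyz1, H2-Ab1 and Mki67. Predicted genes, pseudogenes and genes without a symbol were passed over.

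The tests were tried on simulated counts for 10694 genes with the real means and library sizes, a dispersion of 0.007 and 200 changed genes. In the simulated fraction comparison, edgeR recovered 93% of the genes changed 2-fold and 100% of those changed 4-fold, and 5.39% of its calls were false. In the simulated diet comparison it recovered 93% and 100%, and 3.02% of its calls were false. DESeq2 version 1.42.0 recovered 54% and 92% in the fraction comparison and 60% and 93% in the diet comparison. The simulated libraries were independent, with the same dispersion for every gene and no difference between pools or diet-by-fraction difference. They also held only 200 changed genes, as many higher as lower, whereas 5090 of 10694 genes were called between the real fractions. These rates therefore need not hold for the real libraries. Alternatives covered the scaling, the filter on low counts, DESeq2's Wald test, fits without the block, the pseudocount, the floor and size of the fold rule, thinned counts and shorter gene lists. No library could be left out of the fit, since that leaves no residual degree of freedom.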

Results

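Gene expression was measured by RNA sequencing in GFP-high intestinal stem cells and GFP-low progenitors of old male mice kept on a high-fat diet (HFD) or a control diet. There was 1 library for each of the 4 combinations, each a pool of 2 to 5 mice, so no value below has a replicate of its own group. Total counts ranged from 4677389 to 6207080 per library, 18918 genes had a count in at least 1 library, and 10694 were tested. The series asks how a high-fat diet changes intestinal stem cells and progenitors. The design gives a comparison of the fractions, a comparison of the diets over both fractions, and a comparison of the diets within each fraction.

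The fractions were compared first, as a check of what the sort separated. Stem cell genes were far higher in GFP-high cells. Lgr5, a receptor for R-spondins and the marker of crypt base stem cells, was at 242 and 241 CPM in GFP-high and at 12.5 and 12.7 CPM in GFP-low under HFD and control, 19.1-fold higher in GFP-high (log2 4.26 ± 0.13 SE, edgeR adjusted p = 6.77e-13). Olfm4, a secreted stem cell marker, was 7.31-fold higher in GFP-high (log2 2.87 ± 0.12 SE, edgeR adjusted p = 5.41e-11). Enterocyte and goblet genes were higher in GFP-low, such as Alpi, the intestinal alkaline phosphatase, by 26.8-fold (edgeR adjusted p = 1.74e-10).

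All 28 tested stem cell markers rose in GFP-high (28 also when adjusted over the list alone, DESeq2 27), with a median log2 ratio of 2.13 (interval 2.06 to 2.22). Besides Lgr5, Tnfrsf19, a receptor of the TNF family and a Wnt target, was 16.2-fold higher in GFP-high. Msi1, an RNA-binding protein of stem cells, was 7.99-fold higher. The Wnt target list, which shares 10 genes with the stem cell list, had a median of 1.76, and 14 of 18 genes rose in GFP-high while 2 fell (14 and 2 adjusted over the list alone, DESeq2 14 and 1). The other genes named by rule as higher in GFP-high were Slc1a2, a glutamate transporter (11.3-fold), Pcdh8, a protocadherin (11.4-fold), Extl1, a glycosyltransferase of heparan sulfate synthesis (10.4-fold), Arl4c, a small GTPase (10.2-fold), Limch1 (8.21-fold) and Ccdc3 (7.58-fold).

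Among enterocyte markers, 18 of 21 fell in GFP-high (19 adjusted over the list alone, DESeq2 19), with a median log2 ratio of -3.26 (interval -3.50 to -3.15). The largest differences after the naming rule included Slc9a3, the apical sodium-hydrogen exchanger, 44.4-fold higher in GFP-low, and Apol10a, an apolipoprotein L gene, 38.6-fold higher. Cdkn2b, a cell cycle inhibitor, was 33.9-fold higher in GFP-low. Papss2, an enzyme of sulfate activation, was 22.5-fold higher, and Enpep, a brush border aminopeptidase, 21.7-fold. Rbp2, a retinol carrier, was 20.9-fold higher, and St3gal4, a sialyltransferase, 19.9-fold. Sis, the sucrase-isomaltase of the brush border, was 24.5-fold higher in GFP-low (log2 -4.62 ± 0.45 SE, edgeR adjusted p = 0.017).

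Secretory lineage markers were also higher in GFP-low. The goblet list had a median log2 ratio of -2.96 and 12 of 13 genes fell in GFP-high (12 adjusted over the list alone, DESeq2 13). Zg16, a secreted lectin of goblet cells, was 35.1-fold higher in GFP-low. The enteroendocrine list had a median of -3.12, and 10 of 13 genes fell in GFP-high (10 adjusted over the list alone, DESeq2 11). The Paneth list had a median of -1.23, and 10 of 13 fell (11 adjusted over the list alone, DESeq2 9). Lyz1, the lysozyme of Paneth cells, was 2.49-fold higher in GFP-low (edgeR adjusted p = 2.6e-08). Of the tuft markers 3 were tested, with a median of -0.92, and 2 fell (2 adjusted over the list alone, DESeq2 1).

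Cell cycle genes were higher in GFP-high. In the S phase list, 15 of 16 genes rose (15 adjusted over the list alone, DESeq2 10, median log2 ratio 0.89), and in the G2/M list 16 of 21 rose (18 adjusted over the list alone, DESeq2 8, median 0.44). Mki67, a marker of cycling cells, was 1.44-fold higher in GFP-high (edgeR adjusted p = 0.0005). All 23 cholesterol synthesis genes fell in GFP-high (23 adjusted over the list alone, DESeq2 19, median -0.94), as did 14 of 18 fatty acid oxidation genes (15 adjusted over the list alone, DESeq2 9, median -0.50). The lipid absorption list had a median of -1.92, and 15 of 18 genes fell while 2 rose (16 and 2 adjusted over the list alone, DESeq2 15 and 1). Of the PPAR targets, 16 of 28 fell and 3 rose (16 and 3 adjusted over the list alone, DESeq2 14 and 0, median -0.52). Of the 7 MHC class II genes, 6 rose in GFP-high (6 adjusted over the list alone, DESeq2 5, median 0.83). Of the interferon and MHC class I genes, 10 of 15 fell and 1 rose (12 and 1 adjusted over the list alone, DESeq2 4 and 0, median -0.43). Scaling by library totals moved the medians of the fatty acid oxidation, PPAR and interferon lists to -0.31, -0.33 and -0.24.

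The remaining lists were mixed between the fractions. Of the Notch pathway genes, 5 of 10 rose in GFP-high and 4 fell (5 and 4 adjusted over the list alone, DESeq2 3 and 3, median log2 ratio 0.17, or 0.55 with a filter of 100 counts), and Jag1, a Notch ligand, was 1.5-fold higher in GFP-low (edgeR adjusted p = 0.0189). Of the fatty acid synthesis genes 3 of 12 rose and 4 fell (3 and 4 adjusted over the list alone, DESeq2 2 and 4, median -0.11), and of the ketone metabolism genes 2 of 5 fell (2 adjusted over the list alone, DESeq2 0, median -0.05). Of the immediate early genes 2 of 9 rose and 5 fell (2 and 5 adjusted over the list alone, DESeq2 1 and 3, median -0.44). Of the circadian genes 2 of 10 rose and 2 fell (2 and 2 adjusted over the list alone, DESeq2 1 and 1, median -0.15), of the regional genes 3 of 6 fell (3 adjusted over the list alone, DESeq2 1, median -0.26), and none of the 12 mitochondrially encoded genes was called (DESeq2 0, median -0.15). Scaling by library totals turned the medians of the fatty acid synthesis, ketone, circadian and mitochondrially encoded lists to 0.09, 0.14, 0.04 and 0.04, and moved the regional median to -0.07 and the Notch median to 0.34.

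Over all genes, edgeR called 5090 of 10694 between the fractions (47.6%), of which 2350 were higher and 2740 lower in GFP-high. Each differed in the same direction under both diets, which the additive model favours because a diet-by-fraction difference counts as spread. At least 2-fold changes made up 653 of the higher and 935 of the lower genes. DESeq2's Wald test called 2390 genes, and a fit without diet as a block called 2948. Scaling by library totals moved the median log2 ratio of all genes by 0.188 and gave 3633 higher and 1903 lower.

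**Figure D1:**
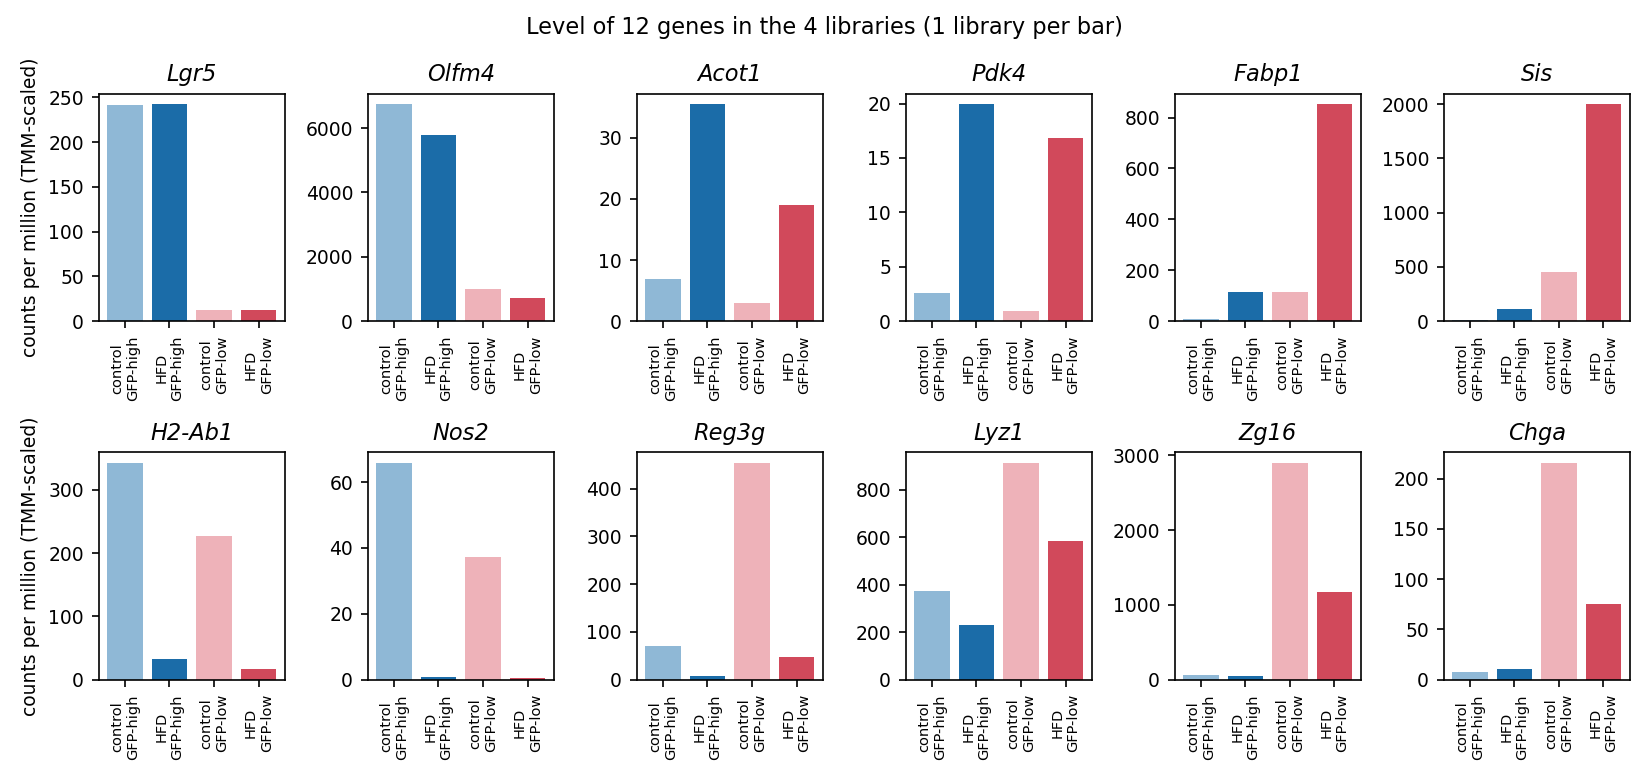
TMM-scaled CPM (vertical axis, linear, from 0) of 12 genes in the 4 libraries, 1 bar per library, with no error bars because no group has a replicate. Lgr5 stands near 242 CPM in both GFP-high libraries, Fabp1 is at 113 and 852 CPM in the HFD libraries against 8.69 and 113 CPM in the controls, and H2-Ab1 is at 32.4 and 16.4 CPM in HFD against 343 and 226 CPM in the controls.

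The diets were then compared over both fractions. Genes of fatty acid use rose under HFD, and genes of antigen presentation fell. Fabp1, a fatty acid carrier of enterocytes, rose 8.99-fold (log2 3.17 ± 0.16 SE, edgeR adjusted p = 3.38e-06). Pdk4, the kinase that holds back pyruvate oxidation, rose 10.3-fold (log2 3.36 ± 0.35 SE, edgeR adjusted p = 1.14e-05). H2-Ab1, the beta chain of an MHC class II molecule, fell 11.8-fold (log2 -3.56 ± 0.12 SE, edgeR adjusted p = 3.99e-11). Nos2, the inducible nitric oxide synthase, fell from 364 and 164 counts in the control libraries to 6 and 2 in the HFD libraries (edgeR adjusted p = 2.77e-10).

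PPAR targets, genes induced by fatty acid-sensing nuclear receptors, rose as a group: 18 of 28 tested genes rose and none fell (23 and 0 adjusted over the list alone, DESeq2 14 and 0). Acot1, an acyl-CoA thioesterase, rose 5.53-fold (edgeR adjusted p = 3.5e-06). Angptl4, a lipoprotein lipase inhibitor, rose 3.12-fold (edgeR adjusted p = 0.000474). Cpt1a, which brings fatty acids into mitochondria, rose 1.57-fold (edgeR adjusted p = 0.000468). Mgll, a monoacylglycerol lipase, and Creb3l3, a transcription factor of lipid metabolism, were 8.39-fold and 4.32-fold higher on average and did not pass the test (edgeR adjusted p = 0.0757 and 0.0775). Vnn1, a pantetheinase, was the lowest of the list in GFP-high, with a log2 ratio of -1.77 there and 0.08 in GFP-low (edgeR adjusted p = 0.5).

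The mitochondrial fatty acid oxidation list, which shares 7 genes with the PPAR list, had 16 of 18 genes that rose and none that fell (17 and 0 adjusted over the list alone, DESeq2 8 and 0). Acadvl, the very long chain acyl-CoA dehydrogenase, rose with a log2 ratio of 1.05 ± 0.10 SE (edgeR adjusted p = 4.32e-06). Its annotated interval overlaps Dvl2 on the opposite strand. Slc25a20, the carnitine carrier, rose with a log2 ratio of 1.01 ± 0.15 SE (edgeR adjusted p = 0.000378). Echs1, an enoyl-CoA hydratase, stood at 0.06 ± 0.11 SE and did not pass (edgeR adjusted p = 0.8). In the lipid absorption list 11 of 18 genes rose and none fell (13 and 0 adjusted over the list alone, DESeq2 4 and 0). In the enterocyte list 9 of 21 rose and none fell (15 and 2 adjusted over the list alone, DESeq2 8 and 0), and 7 of the 19 members outside the PPAR list rose. Alpi rose 3.97-fold (edgeR adjusted p = 3.38e-06) and Rbp2 2.31-fold (edgeR adjusted p = 7.17e-06), while Sis was 5.92-fold higher without passing (edgeR adjusted p = 0.147).

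Other lipid lists had few calls in the test over both fractions. In the fatty acid synthesis list Me1, the cytosolic malic enzyme that supplies NADPH, rose 4.61-fold (edgeR adjusted p = 6.26e-06) and Scd2, a fatty acid desaturase, fell (log2 -1.74 ± 0.13 SE, edgeR adjusted p = 3.74e-06); these were the only calls among 12 genes (1 and 2 adjusted over the list alone, DESeq2 1 and 1). In the cholesterol synthesis list 1 of 23 genes rose and 1 fell (1 and 1 adjusted over the list alone, DESeq2 0 and 1), and the gene that rose was Stard4, a sterol carrier (log2 0.42 ± 0.10 SE, edgeR adjusted p = 0.0237). Among 5 ketone metabolism genes Oxct1, which starts ketone body use, fell (-0.75 ± 0.11 SE, edgeR adjusted p = 0.000524). None rose in the test over all genes, but 1 rose and 1 fell adjusted over the list alone (DESeq2 1 and 1). The highest log2 ratio in this list was 2.42 in GFP-high and 4.20 in GFP-low, so the list was not uniformly flat.

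All 7 tested MHC class II genes fell (7 adjusted over the list alone, DESeq2 7). H2-Aa fell 22.7-fold (log2 -4.51 ± 0.18 SE, edgeR adjusted p = 5.11e-09). Ciita, the regulator of MHC class II transcription, fell with a log2 ratio of -2.12 ± 0.17 SE (edgeR adjusted p = 9.18e-07), and H2-DMa, which loads peptides, with -2.09 ± 0.15 SE (edgeR adjusted p = 2.67e-07), where H2-DMa overlaps Brd2 among others on the opposite strand. Of the interferon-stimulated and MHC class I genes, 12 of 15 fell and none rose (14 adjusted over the list alone, DESeq2 9). Nlrc5, the regulator of MHC class I genes, fell with a log2 ratio of -3.40 ± 0.32 SE (edgeR adjusted p = 4.85e-06), and Psmb8, an immunoproteasome subunit, with -1.83 ± 0.12 SE (edgeR adjusted p = 5.12e-08). Leukocyte transcripts were near the detection limit: Ptprc, the pan-leukocyte marker, had 0 counts in every library, and the 21 leukocyte genes together had 128 and 192 counts in the control libraries and 112 and 142 in the HFD libraries.

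The remaining falls named by rule were single genes of several kinds. Nox1, a superoxide-producing oxidase of the epithelium, fell 64.5-fold, from 219 and 70 counts to 3 and 2 (edgeR adjusted p = 4.55e-08). Its interval overlaps Xkrx on the same strand and Arl13a and Cstf2 on the other. Reg3b and Reg3g, antimicrobial lectins, fell 16.2-fold and 9.72-fold (edgeR adjusted p = 0.0081 and 3.99e-11). Pxdn, a peroxidase of the extracellular matrix, fell 21.4-fold (edgeR adjusted p = 7.97e-07), Ceacam10 15.3-fold (7.97e-07), the transcription factor Barx2 14.9-fold (1.27e-08), and Cd177 14.1-fold (8.28e-07). Prex1, a Rac exchange factor, rose 11.1-fold (edgeR adjusted p = 6.54e-05).

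Among cell type lists, 6 of 13 Paneth genes fell and none rose (9 adjusted over the list alone, DESeq2 4), including Lyz1 by 1.59-fold (edgeR adjusted p = 0.000378). In the goblet list 3 of 13 fell (3 adjusted over the list alone, DESeq2 1) and in the enteroendocrine list 2 of 13 fell (3 adjusted over the list alone, DESeq2 0). None of the 3 tested tuft genes was called. Of the stem cell markers, 2 of 28 rose and 5 fell (2 and 8 adjusted over the list alone, DESeq2 1 and 1). Gkn3, a secreted crypt protein, rose with a log2 ratio of 0.90 ± 0.14 SE (edgeR adjusted p = 0.000672) and Tnfrsf19 fell 1.92-fold (edgeR adjusted p = 0.00467). Lgr5 was not called (log2 0.00 ± 0.11 SE, edgeR adjusted p = 1) and Olfm4 was 1.27-fold lower (edgeR adjusted p = 0.0904). Of the Wnt targets none of 18 rose and 4 fell (5 adjusted over the list alone, DESeq2 1).

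No gene of the G2/M list (21), the S phase list (16) or the Notch list (10) was called for diet, by edgeR over all genes, by edgeR adjusted over the list alone or by DESeq2. Mki67 was 1.09-fold lower (edgeR adjusted p = 0.526), and the Notch ligands Jag1 and Jag2 had log2 ratios of -0.26 ± 0.19 and 0.78 ± 0.43 SE (edgeR adjusted p = 0.485 and 0.33). In the circadian list 3 of 10 rose, namely Nr1d1, Nr1d2 and Tef (4 rose and 1 fell adjusted over the list alone, DESeq2 0). In the immediate early list 2 of 9 fell, Hspa1b and Klf6 (5 fell and 1 rose adjusted over the list alone, DESeq2 0). In the regional list Osr2 rose (log2 0.63 ± 0.13 SE, edgeR adjusted p = 0.00714), and it was the only call among 6 (1 adjusted over the list alone, DESeq2 0). Of the mitochondrially encoded genes 1 of 12 rose, mt-Nd3 (1 adjusted over the list alone, DESeq2 0). The mitochondrially encoded messages took 17.1% and 16.8% of the counts in the HFD libraries and 14.9% and 14.1% in the controls. The HFD GFP-high library stood apart in mitochondrial ribosomal RNA, with 1.18% of its counts against 2.54% to 2.82% in the other libraries.

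Over all genes, edgeR called 691 of 10694 for diet (6.46%), 317 higher and 374 lower under HFD. Of these, 690 differed in the same direction in both fractions. The additive model favours such genes, because a diet-by-fraction difference counts as spread, so this agreement is not a separate result. At least 2-fold changes made up 62 of the higher and 123 of the lower genes. With DESeq2's size factors edgeR called 468, of which 198 were higher and 270 lower. DESeq2's Wald test called 187, and edgeR without fraction as a block called 0, with 149 genes at an unadjusted p under 0.05. These p-values are too small if the fractions of a diet shared mice, and 1 pool of mice per diet and fraction cannot separate diet from other differences between the pools.

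**Figure D2:**
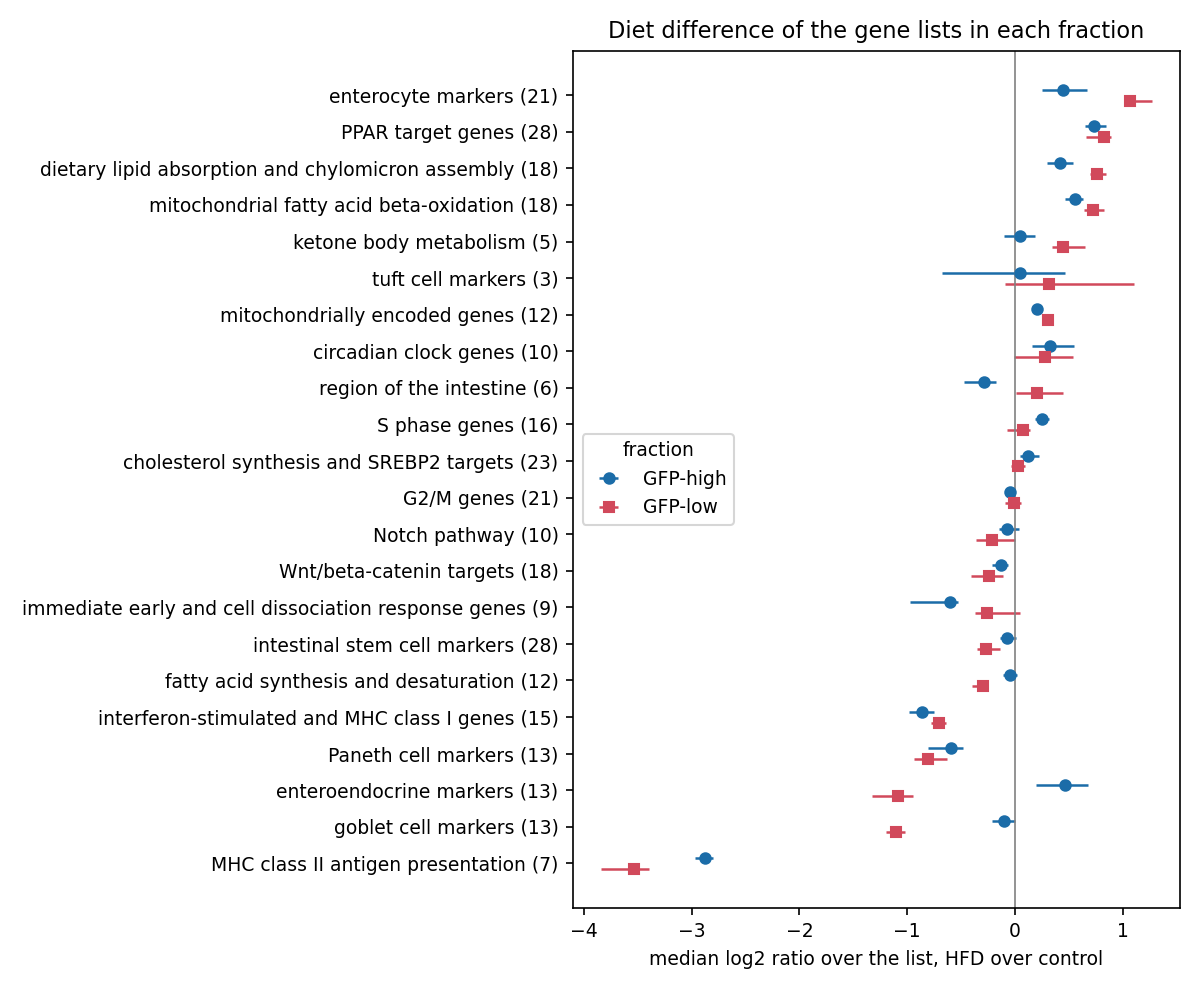
Median log2 ratio of HFD over control (horizontal axis) for each gene list with at least 3 tested genes (number in brackets), in GFP-high (circles) and GFP-low (squares), each from 1 library per diet; bars are 95% intervals from redrawn counts and cover counting error only. MHC class II genes lie at -2.87 and -3.54, PPAR targets at 0.73 and 0.83, and goblet and enteroendocrine markers lie apart in the 2 fractions.

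Within GFP-high stem cells, HFD and control were compared with 1 library each, so the differences have no replicate check. The genes highest under HFD were Mgll, with 142 counts against 3 in control (log2 4.38, interval 3.72 to 7.59), Prex1 (3.65, interval 2.95 to 6.26), Fabp1 (3.63, interval 3.28 to 4.16), Sis (3.38, interval 3.05 to 3.85) and Creb3l3 (3.18, interval 2.64 to 4.26). The lowest were Nos2 (-5.57, interval -7.65 to -5.06), Nox1 (-5.40, interval -8.75 to -4.90), Reg3b (-4.86, interval -5.99 to -4.40), H2-Aa (-4.16, interval -4.59 to -3.88) and Pxdn (-4.04, interval -4.64 to -3.69). Lgr5 was at 242 against 241 CPM (log2 0.00, interval -0.10 to 0.11), and Olfm4 was lower (-0.22, interval -0.24 to -0.20).

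In GFP-high the PPAR target list had a median log2 ratio of 0.73 (interval 0.65 to 0.84) and the fatty acid oxidation list of 0.55 (interval 0.46 to 0.63), both at percentile 100 among matched random lists of these libraries. The enterocyte list stood at 0.45 (interval 0.25 to 0.67, percentile 100), beside a stem cell list at -0.07 (interval -0.14 to 0.01). Without members shared with the PPAR list, the enterocyte median was 0.25 (interval -0.01 to 0.38). MHC class II genes had a median of -2.87 (interval -2.97 to -2.80, percentile 0), interferon and MHC class I genes of -0.86 (interval -0.98 to -0.75, percentile 0) and Paneth markers of -0.60 (interval -0.81 to -0.49, percentile 0). Immediate early genes, which respond to cell dissociation, were at -0.60 (interval -0.97 to -0.53), and at -0.20 with a filter of 100 counts. S phase genes had a median of 0.25 (interval 0.18 to 0.31, percentile 99.99) and G2/M genes of -0.05 (interval -0.09 to -0.01). The median was 0.42 for lipid absorption and 0.33 for circadian genes (0.21 with a filter of 100 counts). It was 0.21 for mitochondrially encoded genes, 0.12 for cholesterol synthesis, 0.05 for ketone metabolism (mean 0.40) and 0.04 for the 3 tuft genes. It was -0.05 for fatty acid synthesis, -0.07 for Notch, -0.13 for Wnt targets and -0.29 for the regional list. By size, 238 of 10249 genes differed at least 2-fold, 83 higher and 155 lower under HFD.

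Within GFP-low progenitors, again with 1 library each and no replicate check, genes among the highest were Pdk4 (3.62, interval 2.80 to 6.12), Cyp4a10, a fatty acid omega-hydroxylase with 68 counts against 3 (3.60, interval 2.73 to 6.65), Efr3b (2.95, interval 2.22 to 4.52) and Fabp1 (2.91, interval 2.79 to 3.06). The lowest were Nos2 (-5.38, interval -9.58 to -4.64), Pxdn (-5.23, interval -9.43 to -4.49), H2-Aa (-4.97, interval -5.95 to -4.47), Ceacam10 (-4.44, interval -5.16 to -4.01) and Cd177 (-4.38, interval -5.37 to -3.87). Lgr5 was at 12.5 against 12.7 CPM (log2 -0.02, interval -0.56 to 0.53), and Olfm4 was lower (-0.46, interval -0.53 to -0.40).

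In GFP-low the enterocyte list had a median log2 ratio of 1.06 (interval 1.02 to 1.27) and the PPAR list of 0.83 (interval 0.66 to 0.89). The lipid absorption list had 0.76 (interval 0.70 to 0.85) and the fatty acid oxidation list 0.72 (interval 0.64 to 0.82). All were at percentile 100 among matched random lists of these libraries. The enterocyte median was 0.86 with a filter of 100 counts, 0.94 with a pseudocount of 2 CPM and 0.95 without PPAR members. MHC class II genes stood at -3.54 (interval -3.84 to -3.39), goblet markers at -1.10 (interval -1.19 to -1.02), enteroendocrine markers at -1.09 (interval -1.33 to -0.94), Paneth markers at -0.80 (interval -0.94 to -0.63) and interferon and MHC class I genes at -0.71 (interval -0.78 to -0.64), all at percentile 0. Stem cell markers were at -0.27 (interval -0.36 to -0.14, percentile 0). Among goblet genes Ccl6, a chemokine, was lowest at -1.78 and Muc2, the main secreted mucin, stood at -1.46. The median was 0.45 for ketone metabolism (mean 0.85). It was 0.31 for mitochondrially encoded genes and for the 3 tuft genes (the tuft mean was -0.07). For circadian genes it was 0.28, or 0.09 with a filter of 100 counts. It was 0.21 for the regional list, 0.07 for S phase, 0.03 for cholesterol synthesis and -0.01 for G2/M. It was -0.21 for Notch, -0.24 for Wnt targets, -0.26 for immediate early genes and -0.30 for fatty acid synthesis. By size, 434 of 10296 genes differed at least 2-fold, 163 higher and 271 lower under HFD.

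The diet differences of the fractions were set side by side. Of 9859 genes above the floor in both fractions, 104 passed the size rule in the same direction, 26 higher and 78 lower under HFD, and none in opposite directions. Independent lists would share 0.736 and 2.41. Across genes, which are not independent replicates, the log2 ratios of the fractions had a Pearson r of 0.55 and a Spearman rho of 0.40. The difference between the fractions has no test, since it uses the last degree of freedom. The list medians of the difference per gene (GFP-low minus GFP-high) were -1.01 for goblet markers (interval -1.08 to -0.95), -1.15 for enteroendocrine markers (interval -1.48 to -0.60), -0.66 for MHC class II genes (interval -1.11 to -0.59), 0.25 for enterocyte markers (interval 0.07 to 0.44), 0.20 for fatty acid oxidation (interval 0.14 to 0.29) and -0.16 for stem cell markers (interval -0.25 to -0.07).

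**Figure D3:**
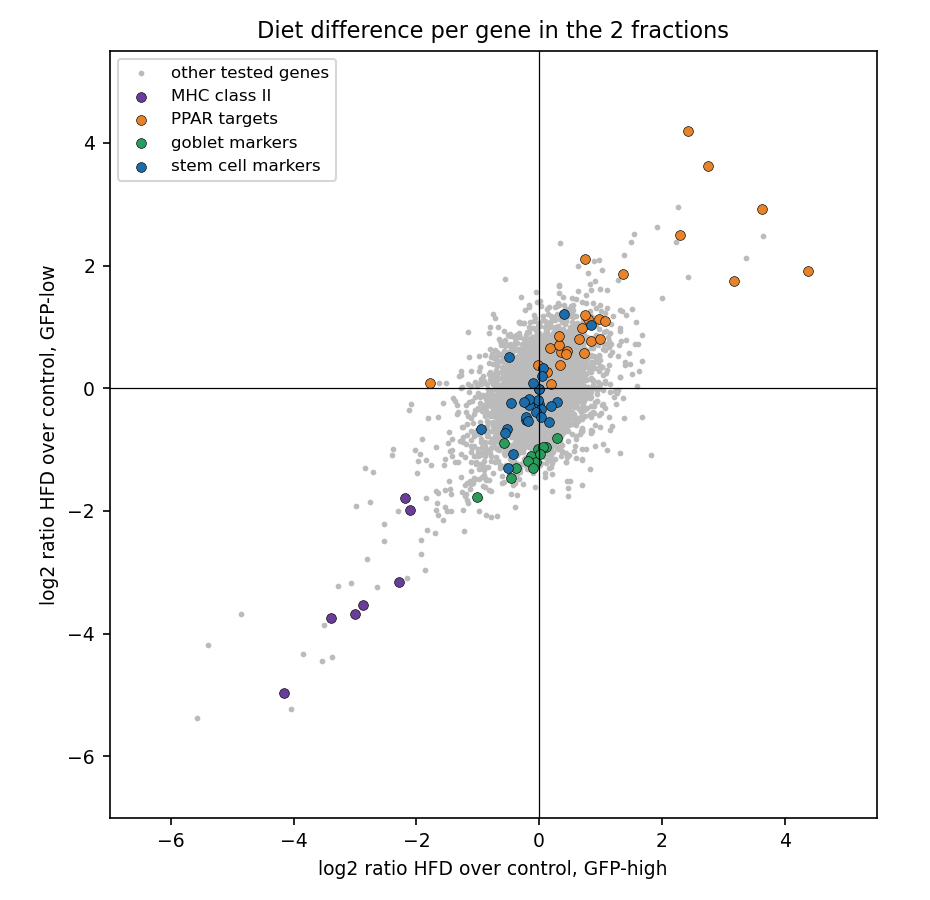
Log2 ratio of HFD over control per gene in GFP-high (horizontal axis) and GFP-low (vertical axis), each point 1 of 10694 tested genes and each ratio from 1 library per diet, with 4 gene lists in colour. The 7 MHC class II genes lie below 0 on both axes, most PPAR targets lie above 0 on both, and goblet markers lie near 0 in GFP-high (median -0.10) and near -1.10 in GFP-low.

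The series title speaks of stemness of progenitors, so the distance between the fractions was compared between the diets. The standard deviation across 10166 genes of the log2 ratio of GFP-high over GFP-low was 0.806 in control and 0.803 in HFD, at equal total counts. The difference was -0.00285 (interval -0.0105 to 0.00349), which includes 0. A second gene set left out the Paneth, goblet, enteroendocrine, tuft, leukocyte, stromal and mitochondrially encoded lists and kept enterocyte genes. Its difference was 0.00868, and by median absolute deviation over all 10166 genes it was 0.0294. Both have the other sign, so the direction depends on the genes and the measure used. The interval was computed for the standard deviation over all 10166 genes and not for these values. By mean log2 ratio, 1564 of 10686 genes differed at least 2-fold by fraction and 242 by diet. By the same rule 26 passed along the diagonal, which holds the diet-by-fraction difference together with noise. The diagonal is that difference halved, so a gene passes only where the diet ratios of the fractions differ by well over 2-fold.

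For position, on GRCm38 with GENCODE M21, Lgr5 (ENSMUSG00000020140) is a protein-coding gene on chromosome 10 from 115450311 to 115587780, and its interval overlaps A930009A15Rik on the opposite strand. Fabp1 (ENSMUSG00000054422) lies on chromosome 6 from 71199827 to 71205023 and Pdk4 (ENSMUSG00000019577) on chromosome 6 from 5483351 to 5496309. H2-Ab1 (ENSMUSG00000073421) lies on chromosome 17 from 34257689 to 34269419 and H2-Aa (ENSMUSG00000036594) next to it from 34282744 to 34287823. Nos2 (ENSMUSG00000020826) lies on chromosome 11 from 78920787 to 78960254, and Reg3b and Reg3g lie on chromosome 6, from 78370657 to 78373466 and from 78466269 to 78468872. All are protein-coding genes.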

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

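All tests of explanations in this part were chosen after the results were seen, and some replaced earlier forms that rested on fewer genes or moved too little to decide. The enteroendocrine list had opposite signs in the fractions, 0.46 in GFP-high and -1.09 in GFP-low, and the median of the differences per gene was -1.15, which was not tested. The regional list was at -0.29 in GFP-high and 0.21 in GFP-low, with a median of the differences per gene of 0.25 that was not tested either, and with a filter of 100 counts its GFP-low median was -0.02. The earlier forms gave 0 counts for 6 leukocyte genes and 0 for Car1, Hoxd10 and Hoxd13 in the control libraries. They also gave a fatty acid oxidation median of 0.57 in GFP-high under library totals and a goblet median of -1.10 in GFP-low under scaling without the most abundant genes, and neither scaling moved its list enough to count for or against anything.

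MHC class II genes fell in HFD in both fractions, with list medians of -2.87 and -3.54. Antigen-presenting leukocytes in the control sorts are argued against: the 10 leukocyte genes outside the T cell group summed to 250 counts in control and 215 in HFD, a ratio of 1.36 after scaling (interval 1.13 to 1.64), against 8.36 for Cd74 (interval 7.93 to 8.81). Itgam made up 191 and 168 of those counts, and without it the ratio was 1.47 (interval 0.983 to 2.20). A different stretch of the small intestine stays open, since the proximal genes Gata4, Onecut2 and Pdx1 had medians of -0.362 in GFP-high and -0.11 in GFP-low, and the distal genes are not used here. With 1 pool per diet and fraction, the diet, which was not tested apart from it, cannot be told apart from the pool of mice, housing or day.

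Fatty acid oxidation genes were higher under HFD in both fractions, with medians of 0.55 and 0.72. GFP-low cells in the HFD GFP-high sort would need a share of 37.0% to give the GFP-high median, and at that share the enterocyte median would be 2.0, against 0.45 observed (interval 0.25 to 0.67). This test replaced a bound on the fatty acid oxidation median itself, which the largest share allowed by the stem cell list, 11.5%, put at 0.20 with HFD GFP-low cells and, by the same bound, at 0.05 with control GFP-low cells. That share would put the enterocyte median at 0.95, so by this list alone a small admixture could account for the higher markers in GFP-high. Goblet and Paneth markers were also higher in GFP-low, yet their GFP-high diet medians were -0.10 (interval -0.21 to -0.0008) and -0.60 (interval -0.81 to -0.49). Enteroendocrine and lipid absorption genes, also higher in GFP-low, went the other way. Their GFP-high diet medians were 0.46 (interval 0.19 to 0.68) and 0.42 (interval 0.29 to 0.54). An admixture of all GFP-low cells would raise the goblet markers too, but no goblet median was predicted at that share. Within counting error, these values argue against an admixture of GFP-low cells as the source of the fatty acid oxidation median in GFP-high. Whether a small admixture raised the enterocyte markers there stays undecided. The diet cannot be told apart from the pool of mice, housing or day, with 1 pool per diet and fraction.

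Goblet and enteroendocrine markers were lower under HFD in GFP-low (-1.10 and -1.09) and not both in GFP-high (-0.10 and 0.46). Counting error in the genes with few counts is argued against for the enteroendocrine list, since the upper bound of the median difference per gene is -0.60. Dilution of every other cell type by enterocytes would lower the G2/M and stem cell genes as much as the goblet genes. The G2/M and stem cell medians in GFP-low were -0.00867 (interval -0.09 to 0.05) and -0.27 (interval -0.36 to -0.14). These values argue only against an equal dilution as large as the goblet fall. The stem cell median did fall, so a smaller dilution is not excluded. A shift among GFP-low cells that spares cycling cells would leave G2/M genes unchanged and was not tested. A different GFP-low gate or sort cannot be told apart from an untested effect of the diet on secretory cells, with 1 sort per diet and fraction.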

How the results depend on the processing

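The balance of the fraction calls turned under library totals, from 2350 higher and 2740 lower to 3633 and 1903, with 4252 of the 5090 genes called in both. The planned legacy form of edgeR's test was the installed default and gave the main values; the newer form and the shortened PPAR and enterocyte lists were chosen after seeing the data. The number of fraction calls moved from 5090 to 2390 with DESeq2's Wald test and to 2948 without the block. The number of diet calls moved from 691 to 1158 without a filter, to 187 with DESeq2 (with 208 adjusted p-values left undefined) and to 0 without the block. Without the block, the difference of the other factor (fraction or diet) counts as spread by construction, and how much of the drop it makes up was not tested. The cause was not tested for DESeq2 either. A floor of 1 CPM, a floor of 20 CPM and a 1.5-fold rule gave 656, 96 and 810 genes past the size rule in GFP-high, 1021, 213 and 1374 in GFP-low, and 190, 47 and 319 in both, and by construction admit more or fewer genes. For the mean over both fractions they gave 499, 126 and 841, and a pseudocount of 2 CPM gave 158. For the fraction, a floor of 20 CPM gave 1020 and the 1.5-fold rule 3432. For the diagonal, pseudocounts of 0.1 and 2 CPM gave 52 and 3 genes, floors of 1 and 20 CPM gave 149 and 7, and the 1.5-fold rule gave 252, so that count rests on low genes. The enteroendocrine difference was -1.65 with a filter of 100 counts, with fewer genes tested. The MHC class II difference (GFP-low minus GFP-high) was -0.50 with a pseudocount of 2 CPM. The difference in spread between the diets was 0.00868 without the secretory, tuft, leukocyte, stromal and mitochondrially encoded lists. It was 0.0294 by median absolute deviation, against -0.00285 in the main form, and the cause was not tested. Depth limits the genes near 0 in HFD: with a pseudocount of 2 CPM the log2 ratio of Nos2 in GFP-high was -4.55 and that of Nox1 -4.09. No library could be left out of the fit, since each group holds 1.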

Other observations

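The tests of T cell genes and of clock genes in this part, and the use of the stem cell list as a test of a hypothesis, were chosen after the results were seen; the list difference itself and the edgeR fit were planned. The genes in this paragraph were chosen after their values were seen, so they stand as single genes and not as a group. Duox2, a hydrogen peroxide-producing oxidase, fell from 715 and 758 counts in the control GFP-high and GFP-low libraries to 121 and 121 under HFD (edgeR adjusted p = 2.77e-10), and its maturation factor Duoxa2 from 39 and 79 to 10 and 14 (edgeR adjusted p = 0.000302). Pla2g2a, an antibacterial phospholipase, fell from 161 and 276 counts to 41 and 34 (edgeR adjusted p = 3.41e-06). Muc13, a transmembrane mucin, fell with a log2 ratio of -0.79 ± 0.10 SE (edgeR adjusted p = 0.000132), Ccl28, a mucosal chemokine, with -0.62 ± 0.10 SE (edgeR adjusted p = 0.000808), and Pigr, which carries IgA into the lumen, with -0.44 ± 0.11 SE (edgeR adjusted p = 0.0271). Reg3a, a related lectin, did not pass (log2 0.52 ± 0.34 SE, edgeR adjusted p = 0.423).

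Transcripts of other tissues were scarce in all libraries. The red blood cell genes summed to 0 or 1 counts per library, the fibroblast, smooth muscle and endothelial genes to 29, 81, 15 and 119 in HFD GFP-high, HFD GFP-low, control GFP-high and control GFP-low, and the leukocyte genes to 112, 142, 128 and 192. Rpph1, the RNA of ribonuclease P, which carries no poly(A) tail in its mature form, was at 28.5, 64.5, 208 and 159 CPM in the same order.

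The hypothesis that HFD brings GFP-low progenitors closer to GFP-high stem cells was tested on the stem cell markers. Their log2 ratio of GFP-high over GFP-low was larger under HFD than in control by a median difference per gene of 0.16 (counting interval 0.07 to 0.25). The direction is opposite to the hypothesis in these libraries, and with 1 library per group the spread between mice is unknown. The fractions were also cut by GFP level, and the gene that drives GFP is not given in the sources used here. If GFP follows stem cell genes, a progenitor that gained them could leave the GFP-low sort. The sort may therefore hold these markers in place, so the hypothesis remains undecided.

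A hypothesis for the lower interferon-inducible and MHC class II genes is fewer T cell transcripts in the HFD sorts, since T cells are a source of interferon gamma. The 11 T cell genes of the leukocyte list summed to 70 counts in control and 39 in HFD, a ratio of 2.10 after scaling (exact interval 1.4 to 3.19). Most of these counts were Itgae, the integrin of intraepithelial T cells, with 39 and 36 counts (ratio 1.27, interval 0.784 to 2.05). A first form of this test left Itgae out and gave 31 against 3 counts and a ratio of 12.1 (interval 3.77 to 61.7), so the size of the difference depends on that gene. The counts are few and come from 1 pool per diet and fraction, so T cells may be a candidate source of the signal, but these values leave it undecided.

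A different time of day at harvest may explain the circadian genes. Nr1d1, Nr1d2, Dbp, Tef, Per1, Per2 and Per3 had medians of 0.62 in GFP-high and 0.85 in GFP-low, with Per1 near 0 (-0.03 and 0.09). Arntl, Npas2 and Clock, of the opposite phase, had medians of -0.15 and -0.43, a mean of -0.29, with Clock at 0.13 and -0.09. A first form without Clock, Per1 and Per2 gave -0.36 for Arntl and Npas2. An effect of the diet on the clock would give the same pattern, and with 1 pool per diet and fraction the harvest time cannot be told apart from it.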
